A study of Danio rerio with 1152 samples.

How the data were processed

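Single cells of zebrafish (Danio rerio) embryos at 50% epiboly, the stage about 6 hours after fertilization when the blastoderm covers the upper part of the yolk, were profiled by RNA sequencing. Each of the 1152 samples is 1 well that was meant to hold 1 cell. The labels place 384 wells in each of 3 experimental batches and name plates 5, 6, 7 and 8 for batch 1. Per the labels' protocols, blastoderm caps were dissected and freed of yolk, and cells were picked by hand. The labels do not say how many embryos gave the cells of a batch.

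The deposited table holds raw UMI counts (unique molecular identifiers, random tags that mark single cDNA molecules) for 13902 genes in the 1152 wells. The submitters' processing notes name Bowtie and the genome build Zv9, and give no version of the aligner. Per the labels' protocols the tag has 5 random bases, so that 1024 different tags exist. The highest count of a gene in a well was 975, and 854 counts lay above 512, in 13 genes. Counts of the most abundant genes were therefore compressed, because different molecules can carry the same tag. Gene symbols are printed in capitals as the deposited table gives them. No symbol began with the prefix used for mitochondrial genes, so that the mitochondrial list could not be tested.

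Wells with at least 2000 detected genes (at least 1 UMI) were kept, which left 1000 cells. The total per kept cell ranged from 5307 to 132749 UMIs. No doublet caller was run, because cells were picked by hand, and wells with very many detected genes were examined separately. Shares carry Wilson 95% intervals, which cover counting error only.

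Enveloping-layer-like (EVL-like) cells were set apart from deep cells by a Gaussian mixture with 2 components. It was fitted to the mean log2(1 + UMIs per 10000) of the seeds KRT4, KRT5, KRT8, KRT18 and CYT1, with a posterior over 0.5 for the higher component. Deep cells were scored for the margin with TA, TBX16, MIXL1, WNT8A, EVE1, NDR1, LFT2 and FGF8A. The dorsoventral score was the mean of CHD, NOG1, GSC, FRZB, DHARMA and FOXA3 minus that of VED, VENT, VOX, SZL and BAMBIA. Scores are means of within-batch z values, made independent of the number of detected genes by linear regression. The top and bottom 1 in 3 of deep cells within each batch were compared. Such classes are ranges of a score and not cell types, and the seeds of a comparison were left out of its tested genes.

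Counts were summed per class and batch, and the 6 sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalization, batch as a block) in R 4.3.3. The batch is the replicate (n = 3) and cells are not replicates. With batch as a block, p-values rest on how the class difference varies between these batches, with the variance moderated over genes. Nothing says that batches came from separate clutches, so this variation may be technical. Genes detected in at least 5% of the compared cells were tested, and calls had a Benjamini-Hochberg adjusted p under 0.05. The plan named limma on mean log values for normalized data and edgeR for counts, and the counts branch applied. SEs of log2 differences were derived as the difference divided by the square root of the F statistic. Levels are UMIs per 10000 as the mean ± SD of the 3 batches. A gene with no count in a class is given a lower bound against a floor of 3 counts over the class.

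Fixed gene lists were tested with camera (limma 3.58.1), with a preset correlation of 0.01 and with an estimated correlation. A list needed 3 tested members. Coherence of a list among deep cells was the mean pairwise Spearman correlation within a batch after regression on detected genes, set against 1000 random lists matched on level. Clusters were made with scanpy 1.11.5 (leiden, resolution 0.5, 10 principal components, 15 neighbours, 957 variable genes centred within batch). A cluster was named from fixed markers with at least 3 detected. The threshold on how many lead a cluster was set after the clusters were seen.

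Named genes are, per comparison, the 12 highest and 12 lowest differences among called genes with the same direction in all 3 batches, skipping clone names. Up to 4 called members are added per list, or up to 2 members of a list without calls. All seeds, and the 3 genes with the largest range between batches, complete the rule. Some genes that the rule names are not reported here. Seeds, lists, the 3 comparisons, their main test and the alternatives not named below as added were fixed before the data were examined. Of these alternatives, the residualised values and the fit without a trend in the prior held errors in their first form, which gave 0 calls for EVL-like cells. Both were corrected after that was seen.

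The fit was tested on simulated sums with 200 changed genes. For the margin comparison (8138 genes) it recovered 88% of genes changed 8-fold, 72% of those changed 4-fold, 54% of those changed 2-fold and 20% of those changed 1.5-fold. For the EVL comparison (8295 genes) these were 94%, 80%, 44% and 36%, and for the dorsoventral comparison (8184 genes) 90%, 80%, 60% and 26%. Unchanged genes made up 3.31%, 2.31% and 6.57% of the calls in the margin, EVL and dorsoventral simulations. The simulation kept the classes fixed and did not cut them from the counts by a score. These shares therefore do not cover calls that arise from the way classes were chosen.

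Alternatives changed the filters, the block, the scale, the classes, the seeds, the replicates, the tool (DESeq2 1.42.0, limma) and the size factors. Added after the data were seen were DESeq2, median-ratio size factors, the mean of log2(CPM + 1), removal of both abundance trends, removal of wells with over 5000 detected genes, removal of 2 near-identical wells, correction for tag collisions, thinning to 20000 UMIs, and regression on the ranks in the coherence measure.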

Results

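The series comprises 1152 single-cell wells of 50% epiboly zebrafish embryos in 3 experimental batches of equal size. The series title names spatial reconstruction as its subject, and the labels give no group other than batch. Median totals per well were 54343 UMIs in batch 1, 43044 in batch 2 and 34597.5 in batch 3. With the filter of 2000 detected genes, 90.4% of wells were kept in batch 1 (Wilson 95% interval 87 to 92.9), 77.1% in batch 2 (72.6 to 81) and 92.97% in batch 3 (89.96 to 95.1). Kept cells had a median of 3657, 3331 and 3177 detected genes in batches 1, 2 and 3. By plate of batch 1, 82, 87, 86 and 92 of 96 wells were kept on plates 5, 6, 7 and 8.

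**Figure D1:**
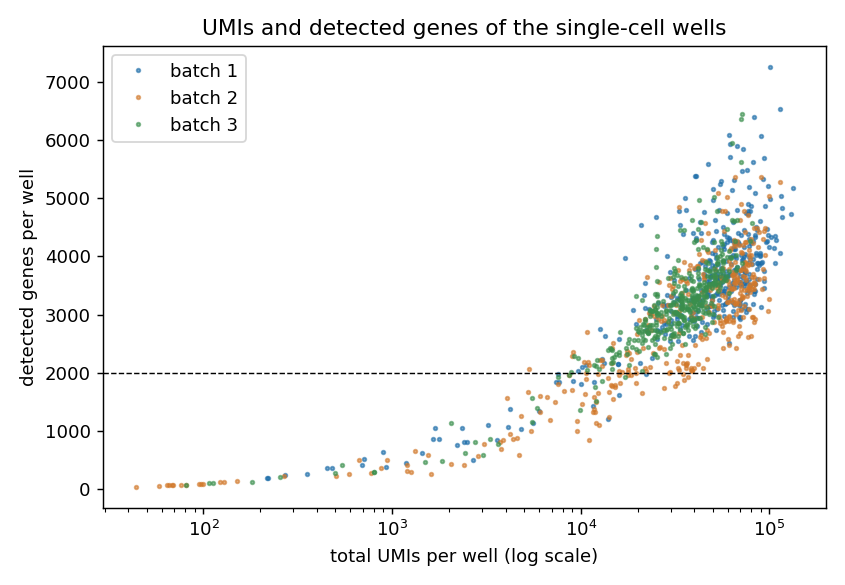
Detected genes per well against total UMIs per well (log scale), each point a well coloured by batch; the dashed line marks the filter of 2000 detected genes, which 1000 of 1152 wells passed.

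A well of batch 1 and a well of batch 2 differed by less than the sampling noise, with a chi-square of 0.50 per degree of freedom over genes with at least 10 UMIs in the pair. The lowest value among the 19 next closest pairs was 1.09. Since cells are not replicates both wells stayed in the sums, and removing both changed no count of called genes in the 3 comparisons. In addition, 39 kept wells had over 5000 detected genes, 28 of them in batch 1, 6 in batch 2 and 5 in batch 3.

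Between batches, which are 1 sample each and were not tested, CX43 (a gap junction protein), FXYD6 and C1QB had the largest range. CX43 stood at 6.63 UMIs per 10000 in batch 3, against 0.0025 in batch 1 and 0.00060 in batch 2. FXYD6 stood at 3.14 in batch 3 and 0.0015 in batch 1, and C1QB at 3.11 in batch 3 and 0.0020 in batch 1. Neither FXYD6 nor C1QB had a count in batch 2, which allows up to 0.0023 UMIs per 10000 as the upper 95% limit. A UMI of CX43 was found in 98.9% of kept wells of batch 3, and in 1 kept well each of batches 1 and 2.

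The cells fell into 8 clusters. A marginal mesendoderm-like cluster held 16.5% of the 1000 cells, with 12.7% of batch 1 (9.58 to 16.6), 13.5% of batch 2 (10.1 to 17.9) and 22.7% of batch 3 (18.6 to 27.3). Its leading genes included MSGN1, MESPAB, MESPAA, FOXC1A, OSR1 and GATA5. A p53 and stress-like cluster of 10.4% of cells was led by MAT2AL, GADD45AA, PHLDA3, FOXO3B and ISG15, and held 10.95% of batch 1, 12.5% of batch 2 and 8.12% of batch 3. An EVL-like cluster held 90 cells. CLDNB was the only EVL marker matched by symbol among its first 10 genes, and its 21 detected markers had a median log2 fold of 2.475. PKP3A was among these 10 too, but the list names PKP3, so PKP3A was not counted. A dorsal-like cluster of 23 cells was led by SIX3B, FRZB, PTF1A, PKDCCA and NOG1, with 3 cells in batch 1, 6 in batch 2 and 14 in batch 3. A cluster of 14.2% of cells led by ADMP, FOXD3, GLI1 and FOXB1A was left unnamed, since its first gene belongs to the dorsal list while 4 of its first 10 belong to the animal ectoderm list. The other 3 clusters, with 18%, 15.7% and 13.9% of cells, had SZL, ICA1 and FLI1B among their leading genes and were left unnamed too.

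The enveloping layer is the outer epithelium of the blastoderm, and the first comparison asked how EVL-like cells differ from deep cells. Of the held-out EVL list 8 of 17 members were higher in the EVL-like cells, though the list as a whole did not pass camera with an estimated correlation (adjusted p = 0.375). CDK1, the mitotic kinase, was the 1 gene called lower. CLDNB, a tight junction claudin, stood at 1.78 ± 1.32 UMIs per 10000 in EVL-like cells and 0.206 ± 0.0131 in deep cells (SD, n = 3). ZNF185 was 10.1-fold higher and the potassium channel gene KCNK1A 10.6-fold higher. CDK1 stood at 1.18 ± 0.124 in EVL-like and 2.01 ± 0.176 in deep cells (SD, n = 3).

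Of 8295 genes tested by edgeR, 96 were higher and 1 was lower. The seeds that define the class stood at 12.9 against 2.23 UMIs per 10000 for KRT18, 5.46 against 0.808 for KRT8, 4.94 against 0.617 for KRT4, 2.29 against 0.271 for KRT5 and 1.87 against 0.239 for CYT1. Other genes among the 12 highest were the fatty acid hydroxylase FA2H (log2 difference 3.00, SE 0.62), the desmosomal plakophilin PKP3A (2.94, SE 0.47), STX11B.1 (2.82, SE 0.51) and CKI (2.80, SE 0.34). HSD17B14 (2.66, SE 0.30), the ceramidase ACER1 (2.64, SE 0.23), the epithelial splicing regulator ESRP1 (2.56, SE 0.29), the calpain CAPN9 (2.55, SE 0.29) and B3GNT5A (2.52, SE 0.34) completed that set. The largest adjusted p among these 12 was 0.0251, for FA2H.

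In the held-out EVL list 8 of 17 tested members rose, none fell and 9 did not pass, with 14 higher when adjusted over the list alone. Of the 34 members fixed for this list, 11 were not found by symbol. PKP3A was not counted, since the list names PKP3. CLDNE (5.59-fold, adjusted p 1.95e-06, edgeR) and the envoplakin gene EVPLA (5.27-fold) were among them. The list's camera adjusted p was 3.04e-43 with the preset correlation, and adjusted p = 0.375 with an estimated correlation. In the animal ectoderm list 2 of 18 members rose, the surface ectoderm regulators GATA3 (3.82-fold) and TFAP2A (3.30-fold), which also made up the 2 of 17 in the ventral and BMP list. With both lists the camera test was not passed (adjusted p 0.221 and 0.44). APLNRA was the 1 of 21 marginal mesendoderm members that rose (2.71-fold), GADD45BA the 1 of 22 of the p53 and stress list (1.87-fold) and ACTB1 the 1 of 13 of the housekeeping list (1.5-fold). In the cell cycle G2M list CDK1 fell and 20 of 21 members did not pass, and the list passed camera as lower (adjusted p 0.00457 preset, adjusted p = 0.517 with an estimated correlation).

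The yolk syncytial layer (YSL) list passed camera as higher in EVL-like cells (adjusted p 0.00343 preset, adjusted p = 0.517 with an estimated correlation), though 0 of 7 members passed singly and 4 did when adjusted over the list alone. HNF4A stood at 0.128 ± 0.0979 against 0.0215 ± 0.0030 and CTSLL at 0.969 ± 0.861 against 0.227 ± 0.0704 (SD, n = 3). Each was higher in 2 batches and lower in 1. The dorsal seeds passed as higher (adjusted p 0.00578 preset) and the ventral seeds as lower (0.0197 preset), each with adjusted p = 0.517 with an estimated correlation. No member of either passed over all genes, and 3 of 4 dorsal and 2 of 5 ventral seeds did when adjusted over the list alone. GSC stood at 0.268 against 0.131 and VENT at 1.02 against 1.34, each with the same direction in all 3 batches. FRZB stood at 0.189 ± 0.1185 against 0.109 ± 0.0816, but was higher in 1 batch and lower in 2. SZL stood at 0.179 ± 0.167 against 0.281 ± 0.0604 (SD, n = 3), lower in 2 batches and higher in 1. The margin seeds, endoderm, organizer, Nodal, FGF, Wnt, germ cell, maternal and ribosomal lists did not pass camera, and none of their members was called.

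The EVL score had no clear gap: 430 of 1000 cells had a posterior between 0.1 and 0.9. EVL-like cells made up 28.5% of batch 1 (24.03 to 33.5), 15.5% of batch 2 (11.9 to 20.1) and 23.5% of batch 3 (19.4 to 28.2). The EVL-like cluster held 11.5% of batch 1 (8.58 to 15.3), 8.11% of batch 2 (5.51 to 11.8) and 7.28% of batch 3 (5.02 to 10.5), and only 34.5% of EVL-like cells lay in it. Plates of batch 1 differed: EVL-like cells made up 32.9% of plate 5 (23.7 to 43.7), 51.7% of plate 6 (41.4 to 61.9), 11.6% of plate 7 (6.44 to 20.1) and 18.5% of plate 8 (11.9 to 27.6), and the cluster 18.3%, 20.7%, 3.49% and 4.35%. CDK1 was the only gene called lower with all batches, but 6 to 31 genes were lower when a batch was left out.

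Cells of the margin, the ring at the edge of the blastoderm, form mesoderm and endoderm, and the second comparison followed this axis. Of the held-out marginal mesendoderm list 19 of 22 members were higher in margin-high deep cells, and of the endoderm list 5 of 7. SOX2, SOX3 and SOX19A were among the 5 of 17 animal ectoderm members that were lower, a list that did not pass camera with an estimated correlation (adjusted p = 0.231). The mesodermal transcription factor gene OSR1 stood at 3.49 ± 1.09 UMIs per 10000 in margin-high and 0.0602 ± 0.0470 in margin-low cells, a 62.6-fold difference (SD, n = 3). SOX3, a neural progenitor factor, stood at 7.97 ± 3.46 against 21.4 ± 1.16 (SD, n = 3).

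Of 8138 genes tested by edgeR, 1.57% were higher and 38 genes (0.467%) lower in margin-high cells. Without batch 1, 88 genes were higher and 21 lower. The seeds stood at 8.31 against 0.601 UMIs per 10000 for EVE1, 4.21 against 0.123 for TA, 4.21 against 0.853 for TBX16, 3.90 against 0.0915 for MIXL1 and 1.18 against 0.0220 for WNT8A. FGF8A stood at 1.17 against 0.0119, NDR1 at 0.641 against 0.0052 and LFT2 at 0.634 against 0.0091. WNT5B stood at 0.189 ± 0.0750 in margin-high cells (SD, n = 3) and had 0 counts in margin-low cells, and so was at least 77.5-fold higher against a floor of 3 counts over the class. MSGN1, a presomitic mesoderm regulator, was 80.2-fold higher (0.638 against 0.0097 UMIs per 10000). WNT8-2 (log2 difference 5.64, SE 0.38), the retinoic acid synthesis gene ALDH1A2 (45.4-fold), MESPAB (5.43, SE 0.43), GATA5 (5.33, SE 0.31), MESPAA (5.21, SE 0.76), KIRREL3L (5.18, SE 0.36), WNT11 (4.97, SE 0.31) and FOXC1A (4.84, SE 0.61) were also among the 12 highest. The levels of WNT8-2, 1.17 against 0.0267 UMIs per 10000, lay close to those of the seed WNT8A. It may therefore not be independent of the seeds. Among the 12 lowest, PRDM14 fell by 3.76 on the log2 scale, KAZALD2 fell by 2.03, PNX fell by 1.84 and PCP4L1 fell by 1.67. SOX3 was 2.88-fold lower, GPD1B 2.78-fold, SOX2 2.66-fold and SOX19A 2.52-fold. ALCAMB (2.31-fold), FAM212AA (2.24-fold), VPS26A (2.02-fold) and the chemokine receptor gene CXCR4B (1.94-fold) were lower as well.

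In the held-out marginal mesendoderm list 19 of 22 members rose and 1 fell, over all genes and adjusted over the list alone. In the endoderm list 5 of 7 rose and 1 fell, with the endoderm determinant SOX32 18.97-fold, the Nodal ligand NDR2 15.8-fold and FOXA2 12.9-fold higher. In the Nodal list 12 of 16 rose and 1 fell (14 and 2 adjusted over the list alone), and in the Wnt list 9 of 17 rose and 1 fell (10 and 2). These 4 lists passed camera with both correlations (each adjusted p = 0.0343 with an estimated correlation). They share members, such as GATA5 in the marginal mesendoderm, endoderm and Nodal lists, and so are not independent results. In the organizer and dorsal list 8 of 15 rose and 1 fell (9 and 2 adjusted over the list alone), with PCDH8 24.5-fold, the Wnt antagonist DKK1B 23.9-fold, LHX1A 23.2-fold and ISM1 21.8-fold higher. In the FGF list 5 of 13 rose and 1 fell (8 and 1), with FLRT3 13.4-fold, SPRY1 8.37-fold, DUSP6 3.54-fold and FGF17 3.38-fold higher. The organizer and FGF lists passed with the preset correlation (adjusted p 1.33e-25 and 1.27e-09) but each had adjusted p = 0.0718 with an estimated correlation.

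Both dorsal and ventral seeds were higher in margin-high cells. FOXA3 (6.81-fold), GSC (5.84-fold) and CHD (2.74-fold) were the 3 tested dorsal seeds and all passed, as did 4 of 5 ventral seeds, VENT (3.46-fold), VED (1.84-fold), VOX (1.35-fold) and BAMBIA (1.25-fold). Their camera calls ended with adjusted p = 0.0944 and 0.172 with an estimated correlation. In the ventral and BMP list 5 of 17 rose (6 and 1 lower adjusted over the list alone), with CDX4 12.4-fold, MSXB 3.63-fold, DRL 3.40-fold and ID3 2.98-fold higher (adjusted p 1.8e-06 preset, adjusted p = 0.176 with an estimated correlation). In the animal ectoderm list 5 of 17 fell and ZIC2A rose 9.55-fold (1 and 6 adjusted over the list alone; adjusted p 2.6e-06 preset, adjusted p = 0.231 with an estimated correlation). GATA6 (4.58-fold), also a member of the endoderm list, was the 1 of 4 YSL members that rose. Adjusted over the list alone 2 rose (camera adjusted p 0.0046 preset, adjusted p = 0.176 with an estimated correlation).

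Lists of other cell states did not pass camera along the margin axis. GADD45BA (5.20-fold) and PMAIP1 (3.86-fold) were the 2 of 21 p53 and stress members that rose. VRTN (1.76-fold) rose and FOXH1 (1.56-fold) fell among 16 maternal and pluripotency members. CXCR4B, also a member of the animal ectoderm list, fell among 12 germ cell members, and HMGB2A (1.17-fold) fell among 13 housekeeping members. None of 15 EVL, 5 EVL seed, 21 cell cycle G2M and 85 ribosomal members passed; the last were taken by name prefix and include kinases such as RPS6KA3B. The comparison used 512 cells, and 23.7% of deep cells lay within 0.1 SD of a class border.

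The third comparison set dorsal-high against ventral-high deep cells. In dorsal-high cells 5 of 13 members of the held-out organizer and dorsal list were higher, and 8 of 17 of the ventral and BMP list were lower. Neither list passed camera with an estimated correlation (adjusted p = 0.0902 and 0.106), a form with few degrees of freedom. The organizer and dorsal list had an estimated correlation of -0.0597, under the preset 0.01, so correlated members do not account for its failure. The ventral and BMP list had 0.141. ADMP, a BMP-family ligand of the organizer, stood at 3.75 ± 0.411 UMIs per 10000 in dorsal-high and 0.405 ± 0.0576 in ventral-high cells (SD, n = 3). BMP4 stood at 0.705 ± 0.206 against 2.55 ± 0.703 (SD, n = 3).

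Of 8184 genes tested by edgeR, 17 were higher and 22 lower in dorsal-high cells. The dorsal seeds stood at 1.97 against 0.117 UMIs per 10000 for CHD, 1.86 against 0.309 for FOXA3, 0.360 against 0.0113 for GSC and 0.101 against 0.0045 for NOG1. FRZB (0.327) and DHARMA (0.0784) had no count in ventral-high cells, and no lower bound was computed for these seeds. Both were sparse, so the zeros say little: FRZB had a UMI in 4.05% to 7.78% of kept cells per batch and DHARMA in 0.28% to 2.36%. For NOG1 this was 2.7% to 5.19%, for GSC 6.42% to 13.5%, for CHD 27.03% to 41.2% and for FOXA3 42.9% to 57.35%. VED, VOX and BAMBIA each had a UMI in at least 95.95% of kept cells of every batch. The ventral seeds stood at 7.32 against 34.3 for VED, 6.19 against 20.1 for BAMBIA, 7.54 against 16.7 for VOX, 0.465 against 2.54 for VENT and 0.0141 against 0.750 for SZL. Higher in dorsal-high cells were FOXD3 (log2 difference 2.23, SE 0.46), OTX1A (2.19, SE 0.31), GADD45BA (1.40, SE 0.16), SLC25A33 (1.15, SE 0.24), the notochord homeobox gene NOTO (1.07, SE 0.11) and IRX7 (1.02, SE 0.17). CST3 (1.94-fold), QKIA (1.49-fold), HIG1 (1.48-fold) and PFKFB4L (1.44-fold) were higher as well. Among genes lower in dorsal-high cells, EVA1BA fell by 5.15 on the log2 scale (0.0038 against 0.124 UMIs per 10000). EVE1 was 8.23-fold lower, MSXC 7.47-fold, CDX4 6.64-fold, MSXB 4.38-fold, FOXI1 4.09-fold, KLF2B 3.56-fold, APOC1L 2.94-fold, ID2A 2.42-fold, BMP7A 2.36-fold and DRL 2.35-fold.

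In the held-out organizer and dorsal list 5 of 13 members rose (9 adjusted over the list alone), and in the ventral and BMP list 8 of 17 fell (10 adjusted over the list alone). Their camera adjusted p were 5.44e-39 and 4.34e-41 with the preset correlation, and adjusted p = 0.0902 and 0.106 with an estimated correlation. In the animal ectoderm list 4 of 17 rose and FOXI1 fell (8 and 3 adjusted over the list alone; adjusted p = 0.114 with an estimated correlation). In the marginal mesendoderm list 4 of 21 fell, among them HER7 (1.66-fold) and HES6 (1.60-fold), with 7 lower and 1 higher adjusted over the list alone and adjusted p = 0.233 with an estimated correlation. The sum of the margin seeds had a median of 11.8 UMIs per 10000 in ventral-high and 3.50 in dorsal-high cells, with EVE1 alone at a mean of 7.68 against 0.897, and CDX4, MSXB and DRL were called along the margin axis too. EVE1 was the 1 of 8 margin seeds that fell (4 adjusted over the list alone; adjusted p = 0.106 with an estimated correlation), and CDX4 and WNT11 (1.53-fold) the 2 of 17 Wnt members (3 lower and 1 higher; adjusted p = 0.165 with an estimated correlation).

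No single member was called in the Nodal and germ cell lists, which passed camera as higher with the preset correlation (adjusted p 0.00807 and 0.00972; adjusted p = 0.568 and 0.69 with an estimated correlation). In the Nodal list DACT2 stood at 0.877 against 0.446, and 3 of 15 members passed when adjusted over the list alone. DND1 stood at 0.673 ± 0.874 against 0.143 ± 0.0316 and NANOS3 at 0.622 ± 0.855 against 0.128 ± 0.0208 (SD, n = 3), and a single well of batch 3 held 511 UMIs of DND1 and 506 of NANOS3. APOEB (1.45-fold lower) was called among 4 YSL members, KLF2B among 16 EVL members and GADD45BA among 22 p53 and stress members, and these lists did not pass camera. The endoderm, FGF, EVL seed, cell cycle, maternal, ribosomal and housekeeping lists did not pass either, with no member called. The counts of this comparison were lower without batch 3, with 5 genes higher and 6 lower, and higher without batch 2, with 36 and 46. Random seed lists matched on level called at least 39 genes in 4 of 50 draws, so the count of called genes alone does not mark this score as special.

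**Figure D2:**
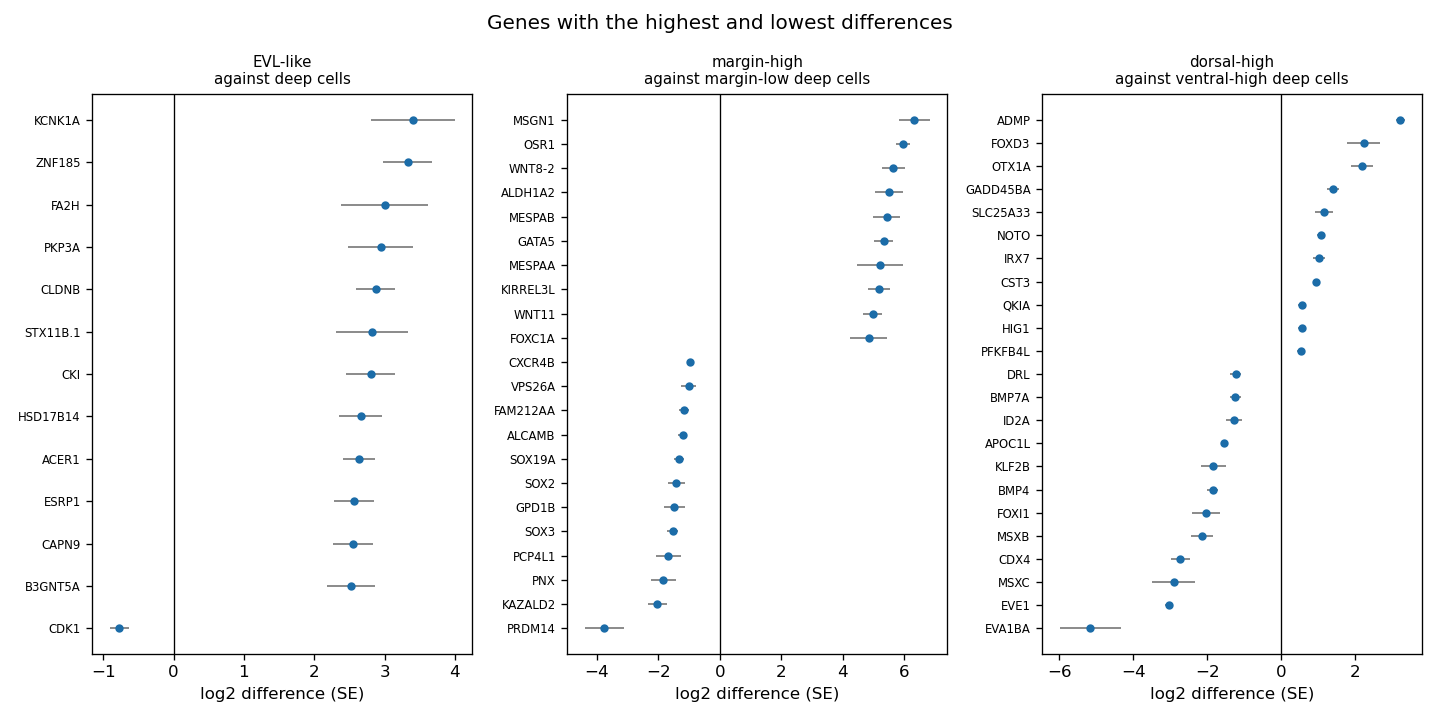
Log2 differences (x axis) of the named genes with the highest and lowest values in the 3 comparisons, drawn as points. Bars are 1 SE, derived from the F statistic of the edgeR test on 3 batches. WNT5B is not drawn because a class had no count. Differences ran up to 3.40 for KCNK1A, 6.32 for MSGN1 and 3.22 for ADMP.

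The last measure asked whether the genes of each list vary together between deep cells of a batch. As fixed in advance, 5 of 20 lists lay at or above the 95th percentile of random lists in all 3 batches: the margin seeds (mean correlation 0.249 ± 0.0677), ventral seeds (0.355 ± 0.0265), EVL seeds (0.222 ± 0.0765), ribosomal proteins (0.0597 ± 0.0034) and housekeeping genes (0.0423 ± 0.0078; SD, n = 3). That measure ranks values after regression, so cells without a UMI of a gene are ordered by their number of detected genes. For GSC, with 88.7% of cells of batch 1 at 0, the correlation with detected genes went from 0.126 before the regression to 0.843 after it. When ranks were regressed instead, an alternative added after this was seen, 16 of 20 lists passed, among them the marginal mesendoderm (0.173), Nodal (0.162), organizer and dorsal (0.116) and p53 and stress (0.0464) lists. The EVL, YSL, germ cell and cell cycle G2M lists did not pass in either form.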

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

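The tests in this part were chosen after the values of CX43, FXYD6 and C1QB had been seen.

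CX43 appeared in wells that no comparison used: the 27 wells of batch 3 under the filter held 46 UMIs of CX43, with 35 of FXYD6 and 32 of C1QB. Wells of batches 1 and 2 that passed the filter held 5 and 1 UMIs of CX43. RNA from a few wells with another cell type is argued against, since the 10% of batch 3 wells with most CX43 held 23.8% of its UMIs. CX43 rose with the total UMIs of a well, with a slope of 0.885 on log scales (95% bootstrap interval 0.787 to 1.04). RNA added in equal amount to each well stays open, because it would be captured and sequenced with the well and so rise with its total too. A difference of batch 3 in strain, reagents or counting stays open and was not tested, since each batch is 1 sample.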

How the results depend on the processing

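DESeq2, median-ratio size factors, log2(CPM + 1) means, removal of both trends, thinning, tag correction, removal of doubted wells and regressed ranks were added after the data were seen. Counts of genes higher and lower were 96 and 1 (EVL-like) and 17 and 22 (dorsoventral); margin results are percents of the genes tested, 1.57% higher and 0.467% lower. With the share of detected cells (limma), and with no trend in the prior or dispersion (edgeR), all 3 comparisons gave 0 and 0; the cause was not tested. With that share BAMBIA stood at -0.0647 along the margin (arcsine scale, adjusted p = 0.785, limma), which says nothing of its direction, since 98.3% to 98.9% of cells had a UMI of it. EVL-like genes lower numbered 3 with a filter of 1000 genes and with log2 of mean CPM, 4 at 3000 genes and with log2(CPM + 10), 0 without the replicate block, 10 with log2(CPM + 1), 9 residualised, 8 with DESeq2, 6 thinned, 7 with stricter posteriors, 12 from the cluster, and 6 to 31 leaving out each batch. Margin genes lower made up 0.209% without the replicate block, 0.713% with log2(CPM + 10), 1.12% residualised and 0.246% with plates as replicates; correlation with the score gave 2.57% higher and 1.24% lower, and leaving out each batch gave 0.266% to 0.648% lower. Dorsoventral counts were 9 and 12 at 3000 genes, 4 and 9 without the replicate block, 9 and 10 with plates, 37 and 42 by correlation, 29 and 43 without FOXA3, and 5 to 36 and 6 to 46 leaving out each batch. Genes higher were 8 with no trend in the prior, 30 with DESeq2, 9 when all deep cells were split at the median score, 11 without VED and 40 without VENT; genes lower were 35 with log2(CPM + 1). The causes were not tested. With an estimated correlation, which leaves few degrees of freedom, 0, 4 and 0 lists passed. Coherent lists numbered 15 without regression and 16 with regressed ranks, against 5. Counting a gene as detected from 10 UMIs gave medians of 1560, 1506 and 1040 genes. Removing the near-identical wells or those over 5000 genes, other size factors and tag correction kept each count within 1.5 times. Of the values of called named genes under alternatives, 10.8% (EVL-like), 13.3% (margin) and 18.2% (dorsoventral) were no longer called.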

Other observations

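The tests of the 2 near-identical wells against 1 shared library, of other splits, of random seed lists and of wells of like depth were written down after their results were seen; the other tests of this part were written down first, on patterns already noticed.

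A single well of batch 3 carried the germ cell program. It held 2590 UMIs of the germ cell list, against 530 in the next well. Its counts were 511 for DND1, 506 for NANOS3, 489 for DDX4, 399 for TDRD7 and 240 for GRA, where the highest other wells held 41, 23, 93, 51 and 58.

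The p53 and stress-like cluster had a median of 3999 detected genes and 57022.5 UMIs, 1.22 times the median of all kept cells. MAT2AL had a UMI in 22.1% of its cells and 1.12% of the others, and PHLDA3 in 33.6% and 2.79%. These genes define the cluster and are no test result.

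The pair of near-identical wells may be 1 library present under both batches: its chi-square per degree of freedom of 0.5003 lay under 1, while the lowest of the 19 next closest pairs was 1.09. That the wells held separate cells of the same kind is argued against. Over genes with at most 50 UMIs in both, where tag saturation plays little part, the value was 0.4577, under the lower 0.1% limit of 0.904 for independent sampling. Which batch the library came from stays open.

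Whether greater depth alone explains the wells with over 5000 detected genes cannot be decided, since they were chosen by detected genes. Of 93 wells of batch 1 with at least their median total, 14 (15.1%) had over 5000 detected genes. The cut at their median fixes that 14. The rest of the 93 show only that detected genes vary between wells of like depth. Thinned to 20000 UMIs, the 28 wells of batch 1 with over 5000 detected genes had a median of 3948, against 2996 in the others. Their choice by detected genes raises this difference. Their median correlation with the mean profile was 0.865, against 0.805 in the others, but among the others this correlation rose with detected genes as well (Spearman 0.737), so it decides nothing on wells chosen by detected genes. RNA of several cells in a well and RNA spread between wells stay open.

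For each comparison, 4 splits of the 6 sums keep the sums of each batch on opposite sides, too few for a share under 0.05. The real split, 1 of the 4, called 97 genes for EVL-like cells, 2.04% of tested genes for the margin and 39 genes for the dorsoventral axis, and the highest of the other 3 called 0 each time. The other 6 splits put both sums of a batch on the same side, which the batch block does not match, and they called 0 as well. Random seed lists matched on level bear on the scores. For the margin, 0 of 50 lists called as many genes, with a highest count of 20. For the dorsoventral axis, 4 of 50 lists called at least 39 genes, with a highest count of 77, so that the number of called genes does not set this score apart from arbitrary seeds.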
